A study of Homo sapiens with 12 samples.

How the data were processed

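RNA sequencing was done on 12 libraries of A549 cells, 1 for each combination of 2 vectors (pBABE empty vector or LKB1), 3 methionine concentrations (58, 115 and 575 µM) and 2 drug arms (vehicle or 60 µM carboplatin). The deposited count table holds expected counts per gene, and the deposited TPM table holds TPM values made by the authors, abundances scaled for transcript length and to one total per library. Both tables list 57905 Ensembl genes with GRCh37 coordinates. The submitters' notes name Trimmomatic 0.39, STAR 2.6.1d and RSEM 1.3.2, without saying how each was set. Of the counts above 0, 11.1% were not whole numbers, and these were rounded. Of the genes, 31942 had no count in any library and 24311 had no symbol.

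Library totals ran from 16700477 to 20333501 expected counts. Counting intervals are at 95% and, like the floor of 3 counts over a group used where all libraries of that group had no count, cover counting error only, since no molecular identifiers were reported. A fold against a group with 1 to 3 counts is a ratio of summed counts over summed depth with an exact binomial interval.

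Counts were tested in R 4.3.3 with edgeR 4.0.16 by quasi-likelihood F-tests (TMM normalization, filterByExpr, robust), which left 15239 genes, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Because no condition had a replicate, the spread came from the factorial layout. The main effects of vector, drug and methionine (a factor with 3 levels) were estimated in an additive model with 7 residual degrees of freedom. The interaction of vector and drug, and the drug effect within each line, came from a model with that term and methionine (6 degrees of freedom), and the interactions of methionine with drug and with vector from models with 5. A contrast of high or low against regular methionine by drug, in a model that also held the vector by drug term (4 degrees of freedom), was added after the data were seen. The biological coefficient of variation in the additive model was 0.125. Expression is given as CPM (counts scaled to the normalized library size), with a prior count of 2 on the log2 scale.

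Of 33 gene lists fixed beforehand, the 30 with at least 5 tested members were tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01, on log2 CPM, and adjusted over lists. Each list was also tested with a correlation estimated from the residuals and with fry. For the main effects these residuals also held the interactions. Members were counted past the threshold over all genes and adjusted over the list alone. Single values were compared by exact sign-flip tests over matched pairs, which cannot go below 0.03125 with 6 pairs or 0.125 with 4.

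Named genes were the 10 largest rises and the 10 largest falls past the threshold, with a mean log2 CPM of at least 1, a symbol and the same direction in every matched pair. For interactions they were the 5 largest each way. To these came the 4 members with the smallest p of each list that passed, of which a part is printed, and 21 anchor genes chosen beforehand. This rule, the lists, the tests and the alternatives were set before the data were examined. For LKB1 against EV the 10 largest rises by the rule were all genes of chromosome Y, which were left out by choice made afterwards, and the next 10 were taken.

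Alternatives were DESeq2 1.42.0, size factors by the RLE method, no filter on low counts, limma-trend on log2 TPM with pseudocounts of 1 and 0.1 for genes with a mean TPM of at least 1, a model with all two-way interactions, methionine as log2 concentration, vehicle or carboplatin libraries alone, the libraries of 1 line alone, and leaving out each library in turn. In such a fit a condition that loses its library is estimated from the others. The fits without the robust step, with the vector by drug term, without chromosome Y, and the list tests within drug arms were added after the data were seen.

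The tests were tried on simulated data with 15239 genes of which 200 were changed. The simulated libraries held no interaction other than a tested one. With 2-fold changes edgeR found 92.5% for carboplatin, 79.1% for low against regular methionine, 68.7% for vector by drug and 49.3% for methionine by drug. Of its calls 7.85%, 7.05%, 7.59% and 13.5% were false, and of those of DESeq2 12.3%, 16.1%, 9.33% and 29.2%. For limma-trend they were 4.97%, 4.83%, 58.2% and 9.09%. The list test found the raised list in each of 3 simulations and called 0 of 29 other lists. The simulated genes varied independently of each other, so this does not test the preset correlation. In the real libraries the estimated correlation was 0.39 for p53 targets and 0.90 for G2/M genes in the additive model.

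The annotation at hand was for another genome build and was not used. Levels of genes of chromosome Y and of XIST are not reported.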

Results

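The series measured gene expression by RNA sequencing in 12 libraries of A549 cells, a human lung adenocarcinoma line that carries mutant KRAS and lacks working LKB1. One line carried the empty pBABE vector (EV), and the other carried LKB1. This kinase is encoded by STK11 and activates AMPK and the salt-inducible kinases. Both lines were kept for 5 days in medium with 58 µM (low), 115 µM (regular) or 575 µM (high) methionine and then given vehicle or 60 µM carboplatin, a platinum drug that crosslinks DNA, for 4 days. Each of the 12 conditions had 1 library and no replicate, so a comparison of lines or of drug arms set 6 libraries against 6, and a comparison of methionine levels set 4 against 4. Total expected counts ran from 16700477 to 20333501 per library, and 18762 to 20069 genes had a count. Expression was compared in 15239 genes, as log2 fold changes with their standard errors (SE) and as counts scaled to library size (CPM) given as the mean ± SD over libraries. The SD covers the other factors as well as noise, and p-values measure how an effect varied over conditions, not over replicate cultures. The first principal component, with 56.7% of the variance, separated the lines, and the second, with 31.2%, separated the drug arms. Markers of blood, stromal and vessel cells were too few among the tested genes for a list test, with 3 of 12 haematopoietic, 4 of 10 fibroblast and 2 of 10 endothelial markers tested. Their highest mean levels were 81.5 TPM (length-scaled transcript abundance) for CD68, 13.1 for COL1A1 and 1.59 for ESAM.

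The first comparison asked how the LKB1 line differed from the EV line. STK11 itself (ENSG00000118046, GRCh37 chromosome 19, 1189406 to 1228428) was higher in the LKB1 line, at 109 ± 3.96 CPM against 68.5 ± 10.3 CPM, a log2 fold change of 0.68 (SE 0.074, adjusted p = 8.15e-06), and in 6 of 6 matched pairs (exact two-sided sign-flip test, p = 0.03125, the smallest that 6 pairs can give). The genes that fell most included LINC00473, a non-coding RNA known from LKB1-deficient lung cancer, which had no count in the LKB1 line and was at least 979-fold lower (floor of 3 counts over the group). GALNT5, FPR1 and NOSTRIN also had no count in the LKB1 line and were at least 429-fold, 393-fold and 197-fold lower. CPS1, the first enzyme of the urea cycle (ENSG00000021826, chromosome 2, 211342406 to 211543831), fell from 522 ± 267 to 8.15 ± 2.52 CPM, a log2 change of -5.89, and INSL4, an insulin-like peptide, fell from 17.6 to 0.0442 CPM. PDK4, which inhibits pyruvate dehydrogenase, fell from 340 to 0.512 CPM, CNTN1 by 11.57 and SMOC1 by 11.21 on the log2 scale. TNS4 fell by 9.76 on the same scale. ASB4 was 1215-fold lower (95% counting interval 336 to 10038) and DMBT1 1199-fold lower (215 to 47407), each from 1 or 2 counts in the LKB1 line.

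Genes higher in the LKB1 line, with chromosome Y left out, included SHISA2, with no count in the EV line and at least 153-fold higher. DIRAS2 was 935-fold higher (95% counting interval 167 to 36976) and COL8A1 537-fold higher (95.9 to 21238), each from 1 count in the EV line. CDH6, a cadherin, rose from 0.255 to 59.3 CPM (log2 fold change 7.81, SE 0.161), and KIAA1211L, CLVS1, CPED1, SLC16A7, MARK1 and PDE11A rose by 6.53 to 7.08 on the log2 scale. CD274, which encodes the checkpoint ligand PD-L1 (ENSG00000120217, chromosome 9, 5450503 to 5470566), was lower in the LKB1 line, at 2.33 against 9.60 CPM (log2 fold change -2.03, SE 0.11, adjusted p = 1.82e-08). It lies on chromosome arm 9p, whose 169 tested genes were also shifted down, by a smaller median of -0.41. TMEM173, which encodes STING, was higher by 1.36 (SE 0.21). CDKN1A, the cell cycle inhibitor p21 (ENSG00000124762, chromosome 6, 36644305 to 36655116), was lower by -0.99 (SE 0.111, adjusted p = 1.57e-05), and MDM2, another p53 target, by -0.34. TRIB3, a target of the amino acid stress factor ATF4, was lower by -1.17 (adjusted p = 0.00436).

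Counted over all genes, 8749 of 15239 passed, 4406 higher and 4343 lower in the LKB1 line, of which 1005 and 1444 changed at least 2-fold. Values that did not pass were 1.90 for the proliferation marker MKI67 (ENSG00000148773, chromosome 10, 129894923 to 129924649, adjusted p = 0.0549), -0.28 for MAT2A, which makes S-adenosylmethionine (ENSG00000168906, chromosome 2, 85766288 to 85772403, adjusted p = 0.569), 0.19 for ASNS (0.272) and -0.58 for CHAC1 (0.187). The other stress and methionine genes that did not pass, ATF4, DDIT3, GDF15, SLC7A11, AHCY, AMD1 and MTAP, lay between -0.15 and 0.08. MTR, which remakes methionine from homocysteine, was higher by 0.22 (adjusted p = 0.00165) but not on TPM (0.26). CBS was higher by 0.36 (0.044), a call lost in 9 of 12 fits that each left out 1 library, all but those without the EV low vehicle, EV regular carboplatin or LKB1 low carboplatin library (up to 0.111). MKI67 passed with DESeq2 (adjusted p = 0.0026) and on TPM (0.0117). MAT2A was 0.16 higher, with an adjusted p of 0.032, without the EV low-methionine vehicle library, which held 1591 CPM against at most 379 in any other. The lines follow each other in the order of the deposited columns, and no batch was labelled.

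**Figure D1:**
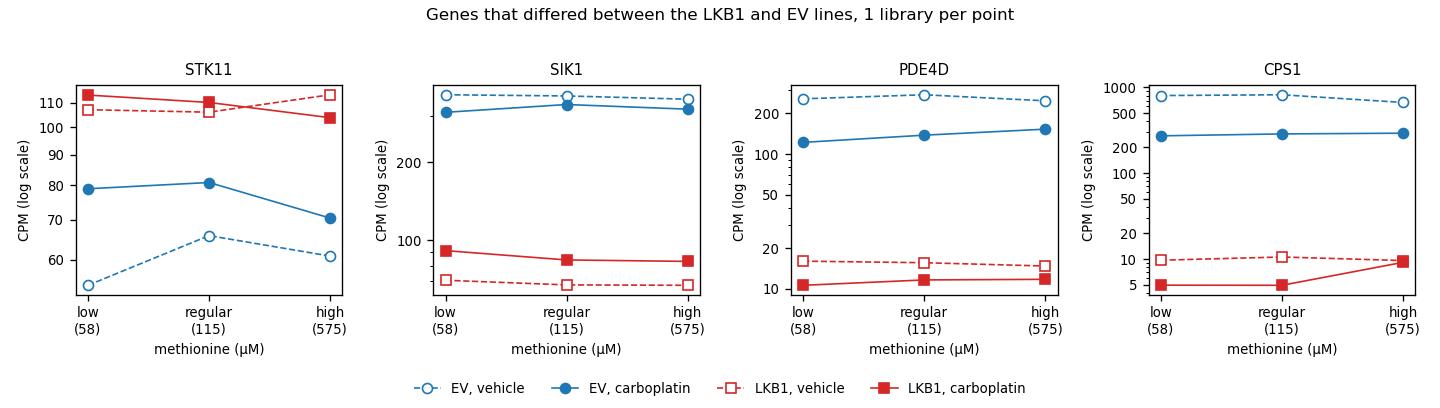
STK11, SIK1, PDE4D and CPS1 in CPM on a log axis against methionine concentration in µM, 1 library per point, with lines joining the libraries of each cell line and drug arm. STK11 averaged 109 CPM in the LKB1 line and 68.5 CPM in the EV line, while SIK1 averaged 77.2 against 339, PDE4D 13.4 against 199 and CPS1 8.15 against 522 CPM.

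Among the 30 gene lists tested, the targets of CREB and its CRTC coactivators, which the salt-inducible kinases hold back, were lower in the LKB1 line. Of 22 tested members 20 fell and 0 rose, also 20 adjusted over the list alone, with a median log2 change of -2.85, and the list was lower in 6 of 6 matched pairs (camera adjusted p = 1.32e-09). Examples were PDE4B at 0.29 against 47.2 CPM, PDE4D at 13.4 against 199 CPM, SIK1 at 77.2 against 339 CPM and PPARGC1A, which was 510-fold lower (95% counting interval 141 to 4218). This list includes genes chosen because earlier work linked them to LKB1 loss. Of 25 interferon-stimulated genes 17 fell and 3 rose, with a median of -0.74 (adjusted p = 0.00263), among them IFI6 (-2.11), MX1 (-2.09) and XAF1 (-3.66). Of 15 genes for MHC class I presentation 11 fell and 0 rose, with a median of -0.24 (adjusted p = 0.00523), among them HLA-F (-1.79), PSMB8 (-0.80) and TAP1 (-0.72). Of 14 genes of the unfolded protein response in the endoplasmic reticulum 12 fell and 1 rose, with a median of -0.36 (adjusted p = 0.00595), among them XBP1 (-0.98) and DNAJB9 (-0.78). None of these 4 list calls held in camera with an estimated correlation. The adjusted p was 0.525 for CREB/CRTC targets and MHC class I, 0.707 for interferon-stimulated genes and 0.765 for the unfolded protein response. For CREB/CRTC targets the estimate was 0.46 in this additive model and 0.015 with the line by drug term. It went from 0.61 to 0.44 for the unfolded protein response, from 0.064 to 0.068 for MHC class I and from 0.22 to 0.24 for interferon-stimulated genes. The lost CREB/CRTC call may thus reflect the omitted term, which was not tested.

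In the other direction, 17 of 22 cholesterol synthesis genes were higher in the LKB1 line and 3 lower, with a median of 0.42 (adjusted p = 0.0025), among them STARD4 (2.27), DHCR24 (1.22) and HMGCS1 (1.02). Of 15 YAP targets and cytoskeletal genes 13 rose and 1 fell, with a median of 0.73 (adjusted p = 0.0025), and ANKRD1 went from 5.29 to 117 CPM. Of 25 genes for G1/S and DNA replication 17 rose and 2 fell, with a median of 0.91 (adjusted p = 0.00263), among them DHFR (1.47), UHRF1 (0.87) and MCM3 (0.59). The pair medians of these genes were 0.20 to 0.57 in vehicle and 1.57 to 2.38 in carboplatin libraries. The 25 G2/M and mitosis genes had a median of 1.25 (adjusted p = 0.00328), but only 4 rose and 21 did not pass, and 0 passed adjusted over the list alone. This median lay between those of the arms, where the pair medians were 0.16 to 0.36 in vehicle and 2.71 to 3.69 in carboplatin libraries. Of the 4 that rose, NDC80, TPX2 and CENPF lost their calls in 8 of 12 fits that each left out 1 library, and KIF23 in 3, at adjusted p-values up to 0.107, each among them without any 1 of the EV carboplatin libraries. With an estimated correlation between genes none of these 4 list calls held either, at an adjusted p = 0.525 for YAP targets, 0.671 for cholesterol synthesis and 0.765 for G1/S and G2/M.

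The comparison of carboplatin with vehicle asked what the drug did across both lines and all media. The p53 targets rose together and the genes of cell division fell. CDKN1A rose from 75.7 ± 33.3 to 1320 ± 496 CPM, 17.7-fold (log2 fold change 4.15, SE 0.124, adjusted p = 1.55e-09), and MDM2 rose by 2.89. MKI67 fell from 643 ± 111 to 88.3 ± 124 CPM (log2 fold change -3.96, SE 0.765, adjusted p = 0.00248). The 10 largest falls were mostly of mitotic genes, with PIF1 (-4.23), CDC20 (-4.10), KIF2C (-4.02), HMMR (-4.01), CCNB2 (-3.99), DLGAP5 (-3.95), TROAP (-3.93), BIRC5 (-3.91) and BUB1 (-3.91) beside MKI67. The largest rises were DRAXIN (7.18, SE 0.464), BLNK at 150-fold (95% counting interval 51.0 to 730), SCN2A (6.14), RGMA (5.75), NBEAP1 (5.42), TNFSF14 (5.36), GRIN2C (5.35, SE 0.151), SLC52A1 (5.22), PVRL4 (5.21) and FLG-AS1 (4.65). Over all genes 9639 passed, 4813 higher and 4826 lower, of which 1227 and 1092 changed at least 2-fold. On TPM the median of all genes shifted by -0.13 under carboplatin, and 2678 genes were higher and 5463 lower, so small changes are relative to the scaling chosen.

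All 30 tested p53 targets rose, also 30 adjusted over the list alone, with a median log2 change of 1.80 (camera adjusted p = 3.8e-17), among them SPATA18 (3.49), TP53INP1 (3.29) and FDXR (2.45). All 25 G2/M and mitosis genes fell, with a median of -3.59 (adjusted p = 3.1e-08), among them CENPE (-3.46), AURKA (-2.82) and CCNB1 (-2.82). Of 25 G1/S and replication genes 23 fell and 1 rose, with a median of -2.39 (adjusted p = 1.73e-07), among them MCM6 (-2.80), MCM2 (-2.39) and POLA1 (-2.02). Of 25 genes of the Fanconi anaemia pathway and homologous recombination, which repair crosslinked DNA, 24 fell and 0 rose, with a median of -2.23 (adjusted p = 8.18e-08), among them XRCC3 (-1.63), FANCC (-1.57) and FANCM (-1.21). Of 20 genes of ribosome biogenesis 16 fell and 2 rose, with a median of -0.34 (adjusted p = 0.000197), among them FBL (-1.32) and NPM1 (-0.93). The repair genes fell along with both cell cycle lists, so a fall of repair apart from cell division was not shown. With an estimated correlation the adjusted p was 0.186 for p53 targets, 0.359 for G2/M, 0.337 for G1/S, and 0.319 for the repair and ribosome lists.

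Of 25 interferon-stimulated genes 21 rose under carboplatin and 1 fell, 21 and 2 adjusted over the list alone, with a median of 1.39 (camera adjusted p = 1.76e-05), among them ISG15 (2.44), IFI6 (1.80) and IFIT3 (1.78). Of 15 MHC class I genes 13 rose and 0 fell, with a median of 0.43 (adjusted p = 5.04e-05), among them ERAP2 (1.33), TAP1 (1.24) and PSMB8 (1.05). Of 22 secreted inflammatory and senescence-associated factors 13 rose and 3 fell, with a median of 0.46 (adjusted p = 0.00793), among them IL1B (3.61), IL8 (1.83) and CXCL1 (1.55). TMEM173 rose by 1.61 and the p53 target and stress cytokine GDF15 by 1.36. CD274 changed by -0.31 (adjusted p = 0.0261), a call lost with DESeq2 (0.0513) and in 5 of 12 fits (up to 0.0853), those without the EV low vehicle, EV low carboplatin, EV regular carboplatin, EV high vehicle or LKB1 regular vehicle library. Of 21 lysosome and autophagy genes 16 rose and 1 fell, with a median of 0.51 (adjusted p = 5.66e-05), among them PSAP (0.90) and GABARAPL1 (0.88). All 13 mitochondrially encoded mRNAs rose, with a median of 0.72 (adjusted p = 0.000287), among them MT-ND6 (0.95) and MT-CO1 (0.90). Their share of counts was 3.64% to 4.60% in vehicle libraries, 6.98% to 7.30% in EV carboplatin libraries and 4.87% to 6.63% in LKB1 carboplatin libraries, higher by 2.41 ± 1.01 percentage points (SD) in 6 of 6 pairs (exact two-sided sign-flip test, p = 0.03125). Of 12 heat shock genes 9 rose and 1 fell, with a median of 0.45 (adjusted p = 0.0482), and HSPA4L rose by 1.47. That call was lost, with an adjusted p of up to 0.0695, without any 1 of the EV low carboplatin, EV regular vehicle, EV regular carboplatin, LKB1 low carboplatin and LKB1 high vehicle libraries. When the correlation was estimated the adjusted p was 0.287 for interferon-stimulated genes, 0.186 for MHC class I, secreted factors and lysosome, 0.337 for mitochondrial mRNAs and 0.654 for heat shock.

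Of 17 folate one-carbon genes 14 fell under carboplatin and 1 rose, 15 and 1 adjusted over the list alone, with a median of -0.52 (camera adjusted p = 5.66e-05), among them SHMT1 (-1.52), MTHFD2 (-1.08) and PAICS (-0.75). Of 29 ATF4 targets of the integrated stress response 16 fell and 4 rose, with a median of -0.42 (adjusted p = 0.0328, and 0.0526 without the LKB1 low-methionine carboplatin library). PHGDH, the first enzyme of serine synthesis, fell by 3.09, ASNS by 2.26 (SE 0.141), TRIB3 by 1.304 and ATF4 by 0.82 on the log2 scale. CHAC1, which degrades glutathione, changed by -1.12, and its adjusted p of 0.0192 reached up to 0.0535 without any 1 of the EV low vehicle, EV low carboplatin and LKB1 regular vehicle libraries. Of 18 aminoacyl-tRNA synthetases 12 fell and 2 rose, 12 and 3 adjusted over the list alone, with a median of -0.40 (adjusted p = 0.00272), and AARS fell by 1.28. Of 22 cholesterol synthesis genes 15 fell and 3 rose, with a median of -0.42 (adjusted p = 0.00189), among them MVK (-1.11) and FDPS (-0.77). Of 14 fatty acid synthesis genes 10 fell and 0 rose, with a median of -0.40 (adjusted p = 0.00272), among them SCD (-1.59) and INSIG1 (-1.32). CBS, which draws homocysteine into cysteine synthesis, fell by 1.40, CPS1 by 1.13 and MTR by 0.32, while MAT2A (-0.52, adjusted p = 0.283), MTAP (-0.66, 0.0896) and DDIT3 (-0.26, 0.447) did not pass. SLC7A11 rose by 0.37 and AHCY by 0.25, neither of which passed on TPM. AMD1 changed by -0.19 (adjusted p = 0.0349), a call lost in 6 of 12 fits that each left out 1 library (up to 0.1), those without the EV low vehicle library or any LKB1 library but the high carboplatin one. With an estimated correlation the adjusted p was 0.186 for folate, 0.654 for the stress response, 0.288 for the synthetases, and 0.319 for both lipid lists.

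**Figure D2:**
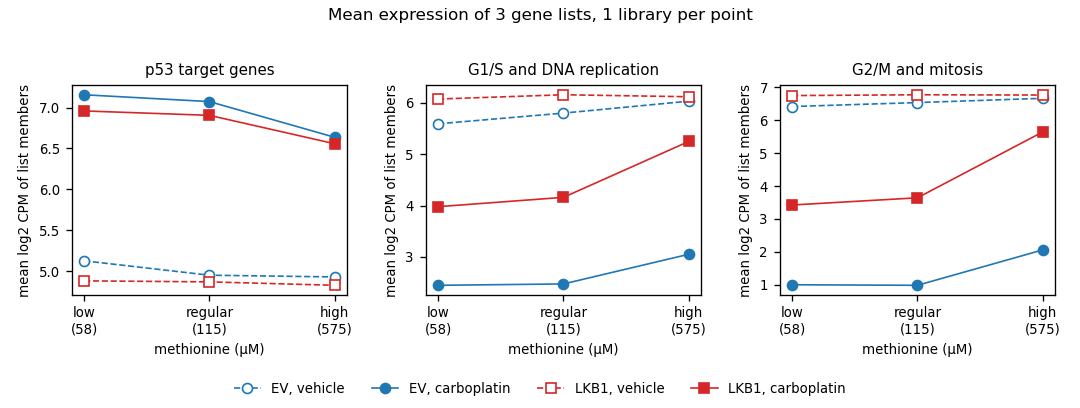
Mean log2 CPM over the members of 3 gene lists, p53 targets, G1/S and replication, and G2/M and mitosis, against methionine concentration in µM, 1 library per point, with lines joining the libraries of each cell line and drug arm. Under carboplatin the mitosis list stood at 0.99, 0.98 and 2.05 in the EV line and at 3.42, 3.64 and 5.65 in the LKB1 line for low, regular and high methionine, against 6.42 to 6.78 in the vehicle libraries.

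The interaction of line and drug asked whether LKB1 changed the response to carboplatin. The G2/M and mitosis genes had a median log2 change of -5.29 in EV cells and -2.41 in LKB1 cells, and 25 of 25 fell in each. Tested singly, 9 of these 25 and 10 of 25 G1/S and replication genes fell less in the LKB1 line, while 16 and 15 did not pass, and both list calls were lost with an estimated correlation (adjusted p = 0.79). MKI67 changed by -5.68 in EV cells and by -2.41 in LKB1 cells, a difference of 3.27 (adjusted p = 0.0261). E2F2 and MCM10, which drive DNA replication, fell less by 3.89 and 3.66 (E2F2 did not pass on TPM with a pseudocount of 1, adjusted p = 0.141), CCNE2 by 2.77, and the repair genes FANCB and RAD51 by 2.89 and 2.23. CDKN1A rose by 3.96 in EV and 4.34 in LKB1 cells, a difference of 0.38 that did not pass (adjusted p = 0.243), and neither did MDM2, at 0.15. Over all genes 1840 passed, 1052 with a higher and 788 with a lower response in LKB1 cells, 373 and 164 by at least 2-fold. The tests within each line called 9226 genes in EV cells (4611 higher) and 8185 in LKB1 cells (4081 higher). The interaction count was 1132 on TPM with a pseudocount of 1 and 1083 with 0.1, and 1122 without the EV low and 1012 without the EV regular carboplatin library.

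The largest interactions were CKAP2L (4.19), BIRC5 (3.95), TTK (3.94), PBK (3.90) and UBE2C (3.90), mitotic genes whose calls were each lost without the EV low or the EV regular carboplatin library. Those 5 calls were lost in 2 to 10 of 12 fits that left out 1 library, with adjusted p-values up to 0.127, and the MKI67 call in 7, up to 0.0813, among them without either of those libraries. In the other direction PSG4 responded lower by -3.33 (adjusted p = 0.000146) and DSC3 by -3.05. KIAA1211L (-4.06), CCDC180 (-3.28) and KCNB1 (-2.90) lost their calls on TPM, where KIAA1211L was at 0.39 with a pseudocount of 1. KIAA1211L also lost its call in 5 of 12 fits that left out 1 library (up to 0.0718) and CCDC180 in 9 (up to 0.159), both among them without the EV regular vehicle or the EV high vehicle library. TMEM173 rose more in LKB1 cells, by 2.13 against 0.95. STK11 differed by -0.34 (adjusted p = 0.0461), a call lost with DESeq2 (0.0526) and in 8 of 12 fits that left out 1 library (up to 0.144).

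PTGS2, the inducible cyclooxygenase and a CREB target, fell from 84.3 ± 11.9 to 52.1 ± 8.30 CPM in EV cells and rose from 2.75 ± 0.497 to 11.4 ± 1.10 CPM in LKB1 cells (SD, n = 3), an interaction of 2.75 (SE 0.124, adjusted p = 3.24e-08). IRS2 (1.70), PTP4A1 (1.27) and TACC2 (0.73) of the same list also differed. Of the 22 CREB/CRTC targets 8 responded higher in LKB1 cells and 0 lower, 15 and 1 adjusted over the list alone, with a median of 0.80 (camera adjusted p = 2.34e-09). This call held with an estimated correlation (adjusted p = 0.0255), and 17 of the targets fell under carboplatin in EV cells against 5 in LKB1 cells, where 6 rose. Without drug, however, the mean log2 CPM of the list was 1.96 to 2.11 in LKB1 libraries against 5.81 to 5.97 in EV libraries. Members near the floor in the LKB1 line, such as LINC00473 with no count, could hardly fall further. The fewer falls there and the list call cannot be set apart from this low starting level.

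Of 25 G2/M genes 9 responded higher in LKB1 cells and 0 lower, 23 and 0 adjusted over the list alone, with a median interaction of 2.97 (camera adjusted p = 1.05e-12). For G1/S and replication 10 of 25 were higher (15 adjusted over the list alone, median 1.19, adjusted p = 5.52e-09). For repair of crosslinks 12 of 25 were higher (15 adjusted over the list alone, median 1.58, adjusted p = 9.26e-06), in the same direction as both cell cycle lists. Of 14 genes of the unfolded protein response 7 were higher, 10 adjusted over the list alone, with a median of 0.39 (adjusted p = 0.000132), among them PDIA4 (0.49) and HYOU1 (0.45). Of 21 mesenchymal and matrix genes 9 were higher and 2 lower, 11 and 2 adjusted over the list alone, with a median of 0.32 (adjusted p = 0.00238), among them FN1 (1.23) and COL6A1 (0.78). Of 25 interferon-stimulated genes 4 responded lower in LKB1 cells, among them STAT1 (-0.64) and IFIT3 (-0.64), 1 responded higher and 20 did not pass. Their median was -0.41 and their mean -0.02 (SD 1.04), with an adjusted p of 0.0108, and 0.0588 without the LKB1 low-methionine vehicle library. In low methionine they rose by a median of 0.91 in LKB1 and 0.72 in EV cells. Immediate early genes (median 0.45, 5 of 15 higher, adjusted p = 0.0306) and heat shock genes (median -0.20, 1 of 12 lower, adjusted p = 0.0328) lost their calls in 4 (up to 0.0718) and 6 (up to 0.437) of 12 fits that left out 1 library, among them those without the EV low vehicle or the LKB1 low vehicle library. Of these, KLF4 was at 0.98 and BAG3 at -0.70. The adjusted p with an estimated correlation was 0.79 for G2/M, G1/S and the unfolded protein response, 0.857 for repair, mesenchymal, interferon-stimulated and heat shock genes, and 0.679 for immediate early genes.

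The methionine comparisons asked what low and high methionine did relative to regular medium. No gene passed with edgeR in either, averaged over both lines and drug arms. For low against regular methionine 0 of 15239 passed, with 261 at an unadjusted p under 0.05 against 762 expected by chance, and DESeq2 called 1, ENSG00000267303. For high against regular methionine 0 passed, with 778 under 0.05, and DESeq2 called 5, the p53 target TP53INP1 (-0.50), DIO2 (0.71), MOK (0.41), MSANTD3-TMEFF1 and ENSG00000267303. For low against high methionine 0 passed, with 1405 under 0.05, and DESeq2 called 14. No gene of these comparisons met the naming rule, and none of the 21 genes followed by name passed, the largest values for low against regular being 0.88 for CHAC1, 0.86 for MAT2A, 0.69 for DDIT3 and 0.47 for TRIB3. In data with simulated changes the same test found 79.1% of 2-fold and 43.3% of 1.5-fold changes in the low against regular comparison, so the smaller changes would often be missed. The simulated libraries held no interaction of line and drug, so these shares may not hold for the real libraries. There that interaction stays in the spread, with a biological coefficient of variation of 0.125 against 0.0852 in the model with that term. In the vehicle libraries alone 3 genes passed for low against regular, 1 for high against regular and 6 for low against high. In the carboplatin libraries alone the counts were 0, 423 (243 higher, 180 lower) and 994 (427 higher, 567 lower), and with all two-way interactions in the model they were 4, 319 and 619. The 3 genes in vehicle were GDF15 (0.61), CLDN2 (-0.72) and the readthrough gene MSANTD3-TMEFF1, the 1 gene was SLX1A-SULT1A3, and the 4 with two-way interactions were CP, CLDN2, MUC5AC and MSANTD3-TMEFF1. Apart from GDF15, 1 of the 21 genes chosen beforehand, these genes and those called by DESeq2 were chosen after their values were seen.

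In low methionine, ATF4 targets of the integrated stress response ranked high among all genes (median 0.20, camera adjusted p = 1.74e-07), with 0 of 29 members passing singly. The medians of matched pairs were 0.61 in EV vehicle, 0.16 in LKB1 vehicle, -0.03 in EV carboplatin and -0.02 in LKB1 carboplatin cells. In vehicle alone 11 of the 29 passed adjusted over the list alone, and in carboplatin alone the list had an adjusted p of 0.533 and turned direction. Aminoacyl-tRNA synthetases ranked high with a median of 0.09 (adjusted p = 0.000955), in 4 of 4 pairs. In the carboplatin pairs the medians were close to 0, at 0.02 in EV and 0.003 in LKB1 cells. Altogether 8 lists passed for low against regular, 6 of which lost their call when 1 library was left out. The p53 targets (0.08) lost theirs without the EV low carboplatin or the EV regular vehicle library (up to 0.112) and fatty acid genes (-0.11) without the EV low vehicle library (0.095), and the other 4 lists in 2 to 7 fits. In number 5 and 4 lists passed without the EV low carboplatin and the EV regular vehicle library. With an estimated correlation 0 of the 8 held, the lowest adjusted p being 0.548.

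**Figure D3:**
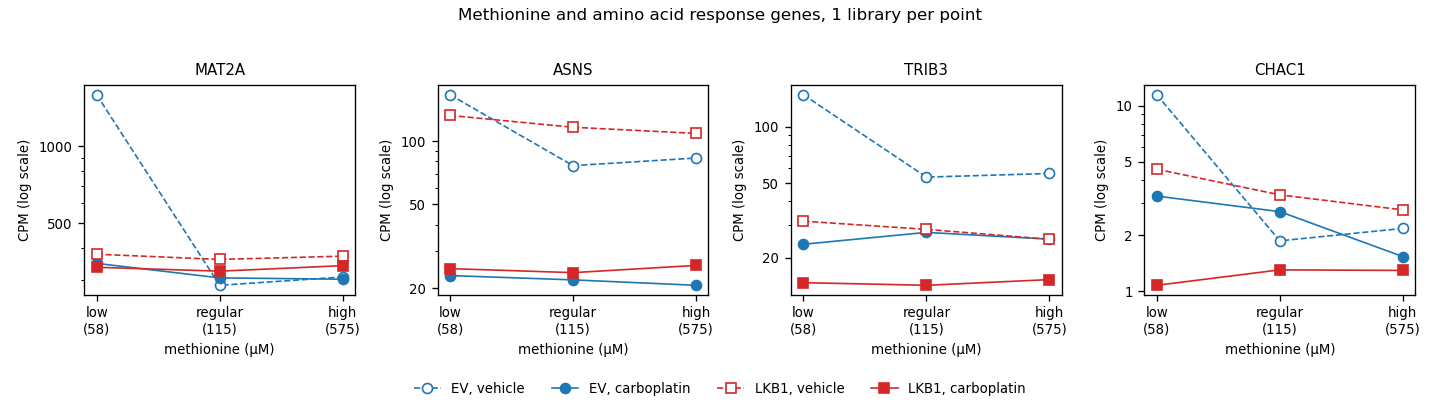
MAT2A, ASNS, TRIB3 and CHAC1 in CPM on a log axis against methionine concentration in µM, 1 library per point, with lines joining the libraries of each cell line and drug arm. MAT2A stood at 1591 CPM in EV cells in low methionine and vehicle and between 287 and 379 CPM in the 11 other libraries.

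In high methionine, the p53 targets ranked low (median -0.22, camera adjusted p = 8.66e-12), by -0.40 in EV carboplatin and -0.32 in LKB1 carboplatin pairs against -0.01 in each vehicle pair. None of the 30 passed singly, and 2 passed adjusted over the list alone. Crosslink repair genes ranked high (median 0.60, adjusted p = 1.77e-06), mostly under carboplatin, where the pair medians were 0.70 in EV and 1.23 in LKB1 cells. In the same carboplatin pairs G1/S genes stood at 0.43 and 1.14, and nucleotide excision repair genes at -0.08 and -0.04. A change of crosslink repair apart from cell division was thus not shown. In vehicle the mean log2 CPM of the crosslink repair genes went from 4.38 in regular to 4.56 in high methionine in EV cells. In LKB1 cells it went from 4.62 to 4.68. Genes of hypoxia and glycolysis also ranked high (0.11, adjusted p = 5.53e-05). The G2/M genes (median 0.87, adjusted p = 4.63e-06) and the G1/S genes (0.48, adjusted p = 1.26e-06) lost their calls without the LKB1 high-methionine carboplatin library, at 0.392 and 0.0602. The pair medians of G2/M genes were 0.93 in EV carboplatin and 1.94 in LKB1 carboplatin cells, against 0.13 and 0.02 in vehicle. Mesenchymal genes (0.15, adjusted p = 0.0024) lost their call without the EV regular carboplatin library (0.151), and 3 more lists lost theirs in 3 fits each. Altogether 9 lists passed, 4 without the LKB1 high carboplatin library, and 0 with an estimated correlation (lowest adjusted p = 0.513).

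For low against high methionine 10 lists passed. The p53 targets ranked higher in low methionine (median 0.30, adjusted p = 5.56e-16, in 4 of 4 pairs), with 0 passing singly and 17 of 30 adjusted over the list alone. Hypoxia and glycolysis ranked lower (median -0.19, 4 of 22 adjusted over the list alone), as did G1/S genes (-0.68, adjusted p = 4.29e-07). The G2/M list (-1.01) lost its call without the LKB1 high carboplatin library (adjusted p = 0.16), and the stress response list (0.22) without the EV low vehicle library (0.134). The BCL2 family (0.10, adjusted p = 0.00843) and repair genes (-0.61) kept theirs in all 12 fits, and the 3 other lists lost theirs in 3 or 4. None of the 10 held with an estimated correlation, the lowest adjusted p being 0.282.

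The last comparison asked whether methionine changed the response to carboplatin or the difference between lines. By the 2-degree-of-freedom test in edgeR 0 genes passed for methionine and carboplatin, with 484 at an unadjusted p under 0.05 and 14 called by DESeq2, and 259 passed once the term for line and drug was in the model. For methionine and line 0 passed, with 120 under 0.05 and 0 by DESeq2. MAT2A passed for methionine and line without the EV low carboplatin library (adjusted p = 0.0046) and for methionine and carboplatin without the LKB1 low vehicle library (0.0204).

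With that term in the model, a contrast added after the data were seen, 170 genes responded to carboplatin differently in high than in regular methionine, 149 higher and 21 lower, and 2 in low methionine. MKI67 stood at 331 CPM in LKB1 cells with carboplatin in high methionine, against 92.1 in regular and 71.5 in low, and at 17.5, 9.09 and 8.30 CPM in EV cells, where vehicle libraries held 520 to 565. CDKN1A reached 1194 CPM in EV cells in high methionine against 1875 in regular and 1945 in low, and 670 against 1100 and 1105 CPM in LKB1 cells. Of 25 G2/M genes 14 passed, all higher, 19 adjusted over the list alone (median 1.63), and of 30 p53 targets 3 passed, all lower, 18 adjusted over the list alone (median -0.35). Of the 25 genes each for G1/S and for repair 7 and 8 passed, and 14 adjusted over the list alone in both (medians 0.85 and 0.85). The adjusted p with an estimated correlation was 0.618 for G2/M, 0.418 for p53 targets and 0.694 for G1/S and for repair. The count of 170 was 87 without the EV regular vehicle, 113 without the EV regular carboplatin, 100 without the EV high vehicle and 360 without the EV high carboplatin library. It was 98 without the LKB1 regular vehicle, 25 without the LKB1 regular carboplatin, 82 without the LKB1 high vehicle and 289 without the LKB1 high carboplatin library. The 2 genes for low methionine were UGT1A9 (1.08) and MSANTD3-TMEFF1, also chosen after their values were seen. For MSANTD3-TMEFF1, which had no count in most libraries, no fold is given. For that contrast 0 were called without the EV low vehicle, EV regular vehicle, LKB1 low carboplatin, LKB1 regular vehicle or LKB1 regular carboplatin library, 1 without the EV or LKB1 high vehicle and 34 without the LKB1 low vehicle library.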

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

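The tests of explanations and of other splits in this part were chosen after the results were seen, while the tests of interaction were planned. An outlying pair of libraries was found in 15 of 195 results tested, where chance gives about 1 in 20.

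The first pattern weighed is the difference between the LKB1 and EV lines in 8749 genes. Other splits of the 12 libraries argue against chance among libraries for this number, since 1 of 100 splits, the real one, gave as many genes (highest other 0). The other splits left the line difference in the spread, which lowers their counts. With 1 line per vector they cannot weigh chance differences between lines. The number of lists alone was reached in 49 of 100 (8 found, highest other 13). This says nothing of a single list such as the CREB/CRTC targets, lower in 6 of 6 pairs by medians of -3.13 to -2.22. A swap of libraries between lines is argued against by STK11, higher in the LKB1 library of 6 of 6 pairs. For genes changed 2-fold or more, copy number of whole chromosome arms as the only cause is argued against. Of these, 91.7% (2232 of 2434) kept 2-fold after their arm's median was subtracted, while smaller changes were not tested. Shifts of whole arms may be a part of it, since 7 of 41 arms, the largest being Xp (-0.86), 9p (-0.41) and 19q (0.41), lay beyond all of 1000 shuffles, whose largest was 0.22. LKB1 itself and any other difference between the lines cannot be told apart, since each vector had 1 line, and the CREB/CRTC list that LKB1 is known to hold down was at -2.85.

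The second pattern is the smaller fall of mitosis genes after carboplatin in high methionine. The median log2 fall was -4.66 against -5.52 in regular methionine in EV cells and -1.15 against -3.14 in LKB1 cells. Cells that escaped the drug, mixed into the EV library, are argued against only as a shared cause of the smaller changes in mitosis genes and p53 targets. Mitosis genes would need 2.06% of such cells (10th to 90th percentile 0.56% to 2.91%) and p53 targets 33.01% (18.0% to 49.9%). A share near 2.06% would by itself account for the mitosis genes, so for them such cells stay open. For the LKB1 library a mixture cannot be told apart from a weaker response, since the shares were 38.6% (31.5% to 45.5%) and 29.1% (8.44% to 43.8%) and their ranges overlap in part. A less active drug in high methionine could account for the pattern, since the rise of p53 targets was smaller in both lines, by -0.37 in EV and -0.32 in LKB1 cells, which does not separate less drug from cells that respond less, and an effect of methionine itself stays open.

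The third pattern is the smaller fall of mitosis genes in the LKB1 line, part of an interaction of line and carboplatin in 1840 genes. A lower mitotic level before the drug is argued against, since the vehicle libraries of the LKB1 line stood higher at each methionine level, by at least 0.16. A weaker response shared by all cells is argued against by the p53 targets. Their log2 rise in LKB1 cells was at least 0.9498 of that in EV cells at each level. Cells that escaped the drug, mixed into the LKB1 libraries, were not tested against the EV response. A small share of them would raise mitosis genes far more than it lowers the p53 targets, so this ratio cannot exclude them. Among 10 splits of the libraries only the real 1 gave as many genes (highest other 0) and 5 gave as many lists as the 9 found (highest other 12), too few splits for a share under 0.05. An effect of LKB1, cells that escaped the drug and any other difference between the lines stay open, untested.

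Chance is argued against for the number of carboplatin genes, 9639, since 1 of 100 splits, the real one, gave as many. The highest other, 5630, came from a split that exchanged 1 library of each drug arm. The other splits left the drug effect in the spread, which lowers their counts. These splits speak for the number and not for each gene. The number of lists alone was reached in 11 of 100 splits (16 found, highest other 17). That tally says nothing of a single list, and p53 targets rose in 6 of 6 pairs, by medians of 1.57 to 1.99, with 30 of 30 members called, and G2/M genes fell in 6 of 6 pairs, by medians of -5.88 to -1.15, with 25 of 25 called. For each methionine comparison the count of genes found was 0, which every split reaches, so the 35 splits of each cannot weigh chance. The highest other counts were 582 for low against regular, 1 for high against regular and 16 for low against high methionine. The split with 582 set EV vehicle and LKB1 carboplatin libraries against the rest. That is the interaction of line and drug, a structure of the samples. The numbers of methionine lists, 8, 9 and 10, were reached in 13, 9 and 14 of 35 splits (highest others 12, 11 and 12), so chance cannot be excluded for these numbers. Within lines 1 of 10 splits, the real one, gave as many as the 9226 carboplatin genes in EV cells and as the 8185 in LKB1 cells (highest other 0 in each), too few splits for a share under 0.05.

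Pairs that stood apart in the difference between lines were, at low methionine in vehicle, TRIB3 at -2.24 (others -1.16 to -0.68) and MAT2A at -2.07 (others -0.05 to 0.34). In the carboplatin response TRIB3 at -2.65 (others -1.16 to -0.71), MAT2A at -2.19 (others -0.17 to 0.10) and SLC7A11 at -0.10 (others 0.40 to 0.53) stood apart in EV cells in low methionine, and PIF1 at -1.71 (others -6.42 to -5.14) in LKB1 cells in high methionine. For low against regular methionine the EV vehicle pair stood apart for ASNS (1.12), AMD1 (0.42), MAT2A (2.47) and DDIT3 (2.08), the EV carboplatin pair for MTAP (1.36, from 11 against 3 counts) and the LKB1 carboplatin pair for INSL4 (0.73, from 3 against 1), and for low against high the EV vehicle pair for MAT2A (2.37). The EV carboplatin pair stood apart in the median of interferon-stimulated genes, at -0.42 for low and -0.27 for high against regular methionine.

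The response to carboplatin differed between lines, by the interaction test, for BIRC5 (3.95), TTK (3.94), PBK (3.90), CKAP2L (4.19), UBE2C (3.90), KIAA1211L (-4.06), CCDC180 (-3.28), PSG4 (-3.33), DSC3 (-3.05), KCNB1 (-2.90), STK11 (-0.34) and TMEM173 (1.18). The calls of BIRC5, TTK, PBK, CKAP2L, UBE2C, KIAA1211L, CCDC180 and STK11 were lost in some fits that left out 1 library. Those of KIAA1211L, CCDC180, KCNB1 and STK11 were lost on TPM. By camera with a preset correlation the response also differed for the lists of G2/M and mitosis (median 2.97), G1/S (1.19), repair (1.58), CREB/CRTC targets (0.80), immediate early genes (0.45), the unfolded protein response (0.39), mesenchymal genes (0.32), interferon-stimulated genes (-0.41) and heat shock (-0.20). With an estimated correlation only the CREB/CRTC call held (adjusted p = 0.0255), and the other 8 were at 0.679 to 0.857. The CREB/CRTC list was already low in the LKB1 line without drug, which limits how far its members could fall. Heat shock, with 1 of 12 members past the threshold, also lost its call in 6 of 12 fits that left out 1 library, those without EV low vehicle, EV low carboplatin, LKB1 low vehicle, LKB1 regular vehicle, LKB1 regular carboplatin or LKB1 high carboplatin (adjusted p up to 0.437).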

How the results depend on the processing

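The settings without the robust step, with the vector by drug term, without chromosome Y, the contrasts of methionine by carboplatin and the list tests within drug arms were chosen after seeing the data; all others were planned. The counts for LKB1 against EV, for carboplatin and for carboplatin within each line stayed within 1.5 times under each setting run for them. Where any of the 570 gene values (355 past the threshold) or 240 list values (73) was past the threshold under either setting, its direction held except as given here. For effects on counts that moved, the cause was not tested unless stated.

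For low against regular methionine the count of genes was 1 with DESeq2, 4 with all two-way interactions and 3 in vehicle alone. For high against regular it was 5 with DESeq2, 319 with all two-way interactions, 2 with the line by drug term, 1 in vehicle alone and 423 in carboplatin alone, and for low against high 14, 619, 25, 6 and 994 in the same order. The line by carboplatin count was 1132 on log2(TPM + 1) and 1083 on log2(TPM + 0.1). For methionine by carboplatin it was 14 with DESeq2 and 259 with the line by drug term, and for the added low-methionine contrast 1 with DESeq2. The fit with both interactions by drug had a biological coefficient of variation of 0.0695, against 0.125 in the additive fit.

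With an estimated correlation 0 lists passed in each comparison, except 1 for line by carboplatin. With fry, which tests members on their own and not against other genes, the numbers were 27 for LKB1 against EV, 0 for low and 0 for high against regular, 1 for low against high, 5 for line by carboplatin, and 0 and 0 for the added contrasts. In carboplatin alone 5 lists passed for low against regular methionine, and in vehicle alone 3 for high against regular.

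These values turned direction. MAT2A for LKB1 against EV was 0.16 without the EV low vehicle library, in a range of -0.42 to 0.16 over libraries left out. For line by carboplatin BRCA2 was -0.19 on log2(TPM + 1) and -0.055 on log2(TPM + 0.1), and KIAA1211L was 0.39 on log2(TPM + 1). By adjusted p, with the direction turned, immediate early genes (0.0164) and epithelial genes (0.0031) did so with fry for LKB1 against EV. In carboplatin alone the stress response and hypoxia did so for low against regular (0.533 each), and the stress response (0.946) and heat shock (0.013) for low against high. For the low-methionine contrast by carboplatin they were cholesterol synthesis without the LKB1 low vehicle library (range over libraries left out 0.000199 to 0.99) and G2/M without the LKB1 low carboplatin library (0.0163, range 0.000883 to 0.951).

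Leaving out each library in turn gave these ranges of counts, with the spread of the lost condition assumed to be like the others. They were 8035 to 8580 for LKB1 against EV (STK11 0.62 to 0.71), 9054 to 9554 for carboplatin, 8118 to 9285 in EV and 6679 to 8473 in LKB1 cells, 0 to 0 for each methionine contrast, 1012 to 2330 for line by carboplatin, 0 to 4 and 0 to 1 for methionine by carboplatin and by line, and 0 to 34 and 25 to 360 for the low and high contrasts by carboplatin. Counts of lists ran from 8 to 11 for LKB1 against EV, 14 to 16 for carboplatin, 4 to 12 for low and for high against regular, 7 to 12 for low against high, 6 to 11 for line by carboplatin, and 4 to 10 and 5 to 8 for the added contrasts. The 4 genes of methionine by carboplatin without the EV high carboplatin library were AURKA, CCNF, POLE and HIST2H4B, the 1 without the LKB1 high carboplatin library was BOLA2, and the 1 without the LKB1 low vehicle library MAT2A. For methionine by line they were MAT2A, BOLA2 and C14orf169, 1 each without the EV low carboplatin, EV high vehicle and LKB1 high carboplatin libraries, and the 2 for high against regular with the line by drug term were GREB1 and DIO2, all but MAT2A chosen after their values were seen. Library totals of 16.7005 to 20.3335 in units of 1e6 limit folds of genes with few counts, and 1 library per condition limits all small effects.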

Other observations

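One library stood apart in genes of amino acid stress. In EV cells in low methionine without drug, MAT2A, whose mRNA is known to be stabilised when S-adenosylmethionine runs low, reached 1591 CPM, 4.20-fold the next highest of the 11 other libraries. The ATF4 targets TRIB3 (148 CPM, 2.63-fold), CHAC1 (11.5 CPM, 2.52-fold), PSAT1 (251 CPM) and ASNS (166 CPM, 1.25-fold), DDIT3 (19.3 CPM, 1.81-fold) and ATF4 itself (307 CPM, 1.12-fold) were also highest in it. SLC7A11, another ATF4 target, was highest in the LKB1 low-methionine carboplatin library (510 CPM). In the LKB1 line the low-methionine vehicle library held 379 CPM of MAT2A and 31.3 CPM of TRIB3, and with carboplatin MAT2A stood at 349 CPM in EV and 337 CPM in LKB1 cells. With 1 library per condition no test sets this library against replicates of its own.

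MTAP, which recycles methionine from a byproduct of polyamine synthesis, averaged 0.723 CPM over all 12 libraries (at most 1.12 CPM). Its neighbour CDKN2A had at most 1 count in any library. KEAP1, which restrains NRF2 and is known to be mutated in this line, had 78.1 ± 5.48 CPM (SD, n = 12), and the NRF2 target AKR1B10 averaged 2891 TPM.

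By camera the 23 NRF2 targets and the 22 genes of the methionine cycle, salvage and polyamines did not pass for LKB1 against EV (adjusted p = 0.334 and 0.374) or for carboplatin (0.994 and 0.0819). The 17 genes of nucleotide excision repair, which removes platinum adducts, did not pass for either (0.675 and 0.253).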
